A study of Mus musculus with 8 samples.

How the data were processed

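Whole-genome bisulfite sequencing was done on liver DNA of male C57BL/6J mice, a common inbred laboratory strain. Per the series description, the mice were 8 weeks old when bought and were then fed for 28 weeks either a normal diet or a diet high in fat, cholesterol and fructose. In bisulfite sequencing unmethylated cytosines are converted and read as thymine, so the share of unconverted reads at a cytosine gives its methylation level. DNA was sheared by sonication, treated with bisulfite and made into libraries, per the labels' protocols. The deposited values are percent methylation per cytosine of a CpG, with each strand on its own row. The submitters' processing notes name FastQC and the genome build mm10. The aligner and the methylation caller are not given in the sources used here.

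The deposited table gives levels and no read counts, so the depth behind each value is unknown and no interval or detection floor was computed from reads. The table as held here ended within chromosome 5. It was read for 15 placed chromosomes, which were chromosomes 1 to 4, chromosome 5 up to position 117098872, and chromosomes 10 to 19, with 30729668 positions. A further 326824 positions on 85 contigs were not used, and 1 incomplete line was left out. Chromosomes 6 to 9, X and Y were not analysed here. The table does not state whether its positions count from 0 or from 1, so a position could be shifted by 1 base, which matters little for means over regions.

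An exact 0 was also written at positions whose neighbours were highly methylated, where it can stand for a position without reads. Such doubtful zeros, defined as a 0 with a median of 50% or more over the 10 nearest positions of the same library, made up 2.01% to 2.40% of positions per library. All zeros made up 12.3% to 13.0% in the libraries titled NASH and 12.8% to 13.1% in those titled WT. The results use the levels as deposited, as fixed before the data were examined. Leaving out the doubtful zeros, or every zero, was added as an alternative after the data were examined. Zeros whose 10 nearest positions had a median of 0 made up 9.1% to 9.4% of positions per library, and such zeros can be truly unmethylated. Leaving out every zero removes them too. It moved CpG-dense positions in gene ends (defined below) from 4.04% to 53.3% in NASH and from 4.17% to 53.2% in ND.

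Samples were grouped by their titles, as 4 libraries titled NASH (nonalcoholic steatohepatitis) and 4 titled WT. The table's column names carry NASH and ND (normal diet) with the same replicate numbers, and the ND columns were taken as the WT-titled libraries because no other group remained. The treatment field of the labels is crossed against the titles: samples titled WT carry the treatment NASH and the reverse. Titles and column names carry the same grouping, which was used, and the libraries are called NASH and ND below. If the treatment field were right instead, every higher and lower given here would be reversed. Nothing in the labels says that the libraries came from separate mice, so p-values of single regions and of means measure the spread between libraries.

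Gene positions came from the RefSeq annotation of GRCm38.p6, the assembly behind mm10. That annotation, as used here, gives no strand, so the promoter fixed in the design could not be told from the other end of a gene. Both gene ends were tested in its place, each from 1000 bases outside to 500 bases inside the gene, for 14808 protein-coding genes. The low end is the one with the smaller coordinate. Regions needed at least 6 positions (3 CpGs on both strands). A region's value was the unweighted mean of its levels in each library. Windows of 1000 bases were tested in the same way. Whole gene spans were added after the data were examined. CpG-dense positions had at least 20 listed positions within a 200-base window.

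Without read counts, the quasi-binomial model planned for reads could not be run, and limma 3.58.1 on the levels, with a mean-dependent prior variance, was used as the design provided for that case. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of single ends, windows and spans are from limma. Genome-wide and class means were compared with exact two-sided permutation tests over the 70 assignments of the libraries, whose smallest p is 0.0286. The 21 gene lists, fixed before the data were examined, were tested with limma's camera on logit levels of gene ends, with an offset of 0.5 positions and a preset correlation of 0.01, and again with an estimated correlation. Camera compares the ends of a list with all other ends, so its p-values do not measure the spread between libraries alone. Of the 449 genes on the lists, 314 had a tested end. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

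The genes named were set by a rule written before the data were examined. The rule takes the 12 largest differences in each direction among called ends whose NASH and ND libraries did not overlap, with overlapping ends counted once. From each list it takes up to 4 called members by smallest p, or, where none was called, the 2 with the smallest p. For windows it takes 5 in each direction. The same rule was applied to gene spans after the data were examined. Some genes that the rule names are not reported here, and the counts of calls include them.

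The tests were tried on simulated levels with the means and spreads of the real libraries and normally distributed noise. Shifted regions were drawn only from those at intermediate mean levels, and no other region was changed. The simulation therefore does not give the power for the real differences, many of which lay at other levels. Of 100 gene ends shifted by 20 points, 57 were called, and of 100 shifted by 10 points, 13. Beside these 57 and 13 true calls there were 8 false calls, from 28748 ends. For gene spans, 100 and 89 of 100 were called, with 13 false calls among 14546 spans. For windows of 1000 bases, 0 of 100 were called at either size among 1597869 windows. The list test was tried on levels in place of logit levels, with ends simulated as independent. It found a list of ends moved by 5 points and called 0 of 20 unmoved lists. Correlation between ends of the real lists was therefore not tried.

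The alternatives covered each library left out in turn, a replicate block, logit levels, library medians removed, wider gene ends, 5000-base windows, a minimum of 4 or 12 positions, a difference of at least 10 points, and the handling of zeros. Settings that need read counts were not run.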

Results

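DNA methylation was measured across the genome in liver of 8 mouse libraries, 4 titled NASH and 4 titled WT (normal diet, called ND here), to compare the liver methylome in steatohepatitis with that on a normal diet. Each library had a level at 30729668 cytosine positions, and the read depth behind the levels is unknown. Values after ± are SDs over n = 4 libraries, differences are NASH minus ND in percentage points, and coordinates are those of mm10.

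Mean methylation over all positions was 71.5% ± 0.584 in NASH and 71.9% ± 0.516 in ND libraries. The difference of -0.423 points was within the spread between libraries (exact permutation p = 0.429, two-sided). CpG-dense positions in gene ends were at 4.04% ± 0.106 and 4.17% ± 0.353, CpG-dense positions elsewhere at 42.2% ± 0.388 and 42.3% ± 0.227, and CpG-sparse positions in gene ends at 57.5% ± 0.445 and 57.6% ± 0.254. CpG-sparse positions inside genes were at 77.7% ± 0.539 and 78.0% ± 0.417, and those between genes at 74.7% ± 0.782 and 75.4% ± 0.757. None of the 5 classes differed by more than the spread (exact permutation tests, Benjamini-Hochberg adjusted p = 0.857 for each).

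Methylation differed at single genes, while no difference in the genome-wide mean was detected. Of 28748 gene ends, 88 were called, 66 with higher and 22 with lower methylation in NASH, and they belong to 87 genes. The called differences had a median size of 17.2 points. Ends that rose had a median ND level of 27.8%, and ends that fell one of 80.8%. NASH and ND libraries did not overlap at 8.36% of all ends, where chance gives 2.86%. The first principal component of gene end methylation, with 28.2% of the variance, separated the NASH from the ND libraries.

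**Figure D1:**
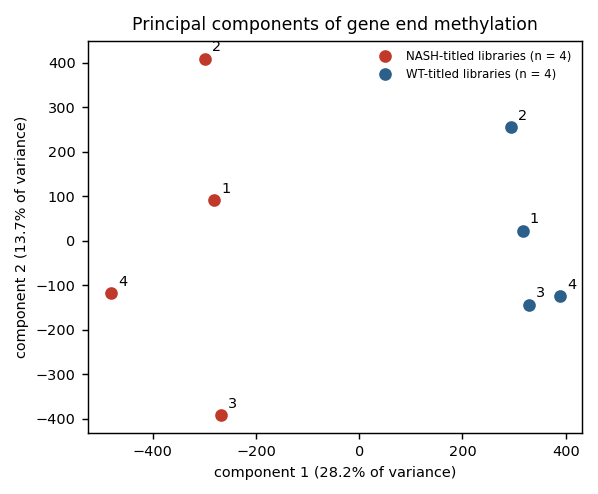
Principal components of the methylation of 28748 gene ends, with component 1 (28.2% of the variance) on the x axis and component 2 (13.7%) on the y axis, one point per library and its replicate number. The 4 NASH libraries lie between -481.3 and -267.4 on component 1, and the 4 ND libraries between 293.5 and 388.9.

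The largest rise was at the low end of Dgkq, a diacylglycerol kinase gene (chromosome 5, 108646044 to 108647544, overlapping Tmem175), from 41.4% ± 3.67 to 70.6% ± 2.04 (29.2 points, SE 2.58, adjusted p = 0.00797). Tmprss6, a hepatocyte protease gene of iron regulation, rose at its high end from 19.6% ± 1.52 to 47.5% ± 7.99. Hal, which encodes the first enzyme of histidine breakdown, rose from 25.7% ± 3.35 to 51.4% ± 8.63. Uox, the urate oxidase gene, rose from 24.7% ± 3.41 to 45.8% ± 3.94 at an end overlapping Dnase2b. The smallest adjusted p, 0.00108, was at the high end of Hsd3b5, a male-biased steroid dehydrogenase gene of mouse liver (chromosome 3, 98645034 to 98646534), which rose from 10.4% ± 1.84 to 34.2% ± 2.13. That end had 14 positions, where the median over all ends was 40. Tm4sf4, Dcun1d1, Cnpy3, Trabd, Rpl32l and Serpina1e also rose, by 22.1, 22.9, 23.1, 25.8, 25.3 and 27.8 points. Serpina1e belongs to a family of near-identical genes and Rpl32l resembles a ribosomal protein gene, so their reads may have been shared with copies and their values are uncertain. The Rpl32l end also overlaps Map7.

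The largest fall was at the low end of Scube1 (chromosome 15, 83601583 to 83603083), from 78.3% ± 4.67 to 49.3% ± 8.91 (-29.0 points, SE 4.44, adjusted p = 0.0444). The end shared by Abcg8 and Abcg5, the genes of the sterol exporter of liver and gut (chromosome 17, 84675302 to 84676802), fell from 72.2% ± 7.65 to 45.4% ± 5.87 (adjusted p = 0.0463). Evi2b, a leukocyte membrane protein gene that overlaps Nf1 and Evi2, fell from 80.9% ± 5.74 to 59.2% ± 3.37. Cysltr2, a leukotriene receptor gene, fell from 74.2% ± 2.61 to 56.8% ± 1.76, and Rasal3, a Ras GTPase-activating gene of blood cells, from 84.4% ± 2.53 to 71.8% ± 1.78. Rgs14 and Rgs18, regulators of G protein signalling, differed by -21.0 and -14.5 points. Ifi204, an interferon-inducible gene, and Ly6a, a surface antigen gene, differed by -16.4 and -17.3 points. Agap2, Sh2d3c and Ripor2 differed by -19.5, -18.5 and -12.7 points, each with an adjusted p under the threshold.

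**Figure D2:**
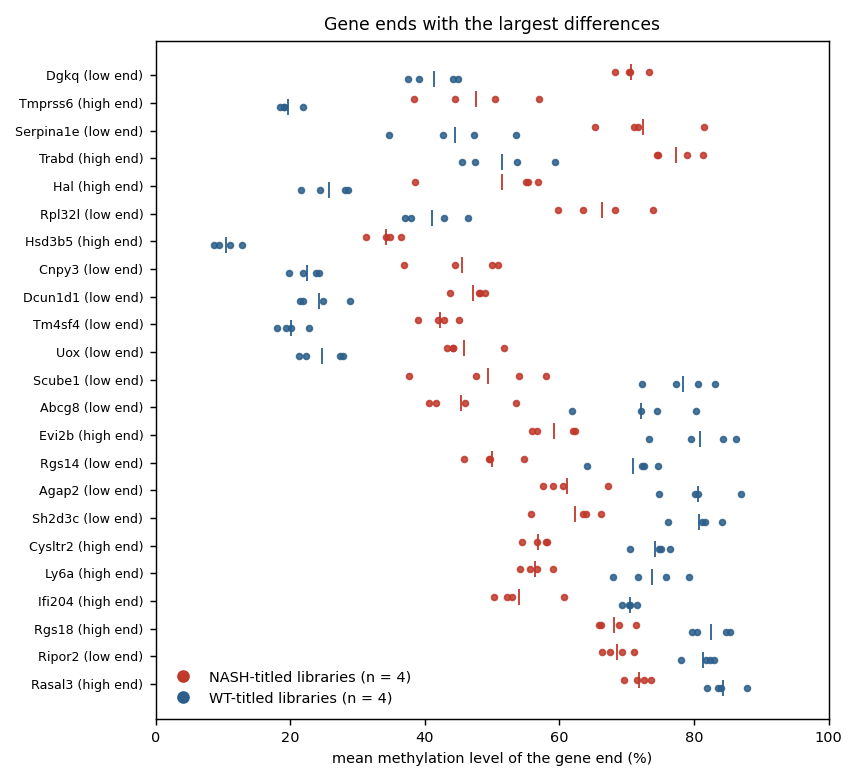
Mean methylation level (%) of 11 of the 12 gene ends with the largest rises and of the 12 with the largest falls, with a point per library and a vertical tick at the mean of each group of 4. At Hsd3b5 the NASH mean is 34.2% and the ND mean 10.4%, and at Scube1 the means are 49.3% and 78.3%.

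The gene end calls depend on having all libraries. With 1 library left out, between 2 and 15 ends were called. Leaving out doubtful zeros, a setting added after the data were examined, gave 109 called ends, 82 higher and 27 lower. It ended the calls at Trabd, Scube1, Agap2, Sh2d3c, Ly6a, Ifi204, Ripor2 and Rasal3 (limma adjusted p from 0.052 at Ripor2 to 0.112 at Ly6a), and with every zero left out no end passed, with 3313 at an unadjusted p under 0.05.

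Hepatocyte identity genes had the clearest shift of the lists. Their 36 ends averaged 41.5% ± 1.82 in NASH and 33.1% ± 0.44 in ND libraries, 8.33 points higher (camera adjusted p = 1.02e-16, and adjusted p = 0.00197 with an estimated correlation), and 34 of the 36 were higher in NASH. Both p-values compare these ends with the other ends, so they do not measure the spread between libraries alone. The estimated correlation was 0.0057, below the preset 0.01, so a higher correlation is not why the second p is larger. Over all ends 4 rose and 0 fell, and adjusted over the list alone 20 rose and 1 fell. The low end of Apoa2 (an apolipoprotein gene), which overlaps Tomm40l, rose from 8.10% ± 1.42 to 15.6% ± 1.11. The low end of Ttr (transthyretin) rose from 31.9% ± 3.60 to 51.2% ± 4.86. The high end of Serpina1a rose from 27.0% ± 2.18 to 39.0% ± 2.48, with the same doubt over shared reads. In the same libraries, the neutrophil list averaged 3.62 points lower.

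Lists of liver metabolism also had higher methylation. Among 34 ends of cholesterol synthesis and uptake genes the mean difference was 3.37 points and the median 1.32. The camera adjusted p was 8.16e-05, and 0.025 with an estimated correlation. Of these ends 1 was called over all ends, and 5 were higher when adjusted over the list alone. The bile acid list was 4.04 points higher (camera adjusted p = 9.34e-05, and 0.0179 with an estimated correlation). Adjusted over this list alone, 9 ends were higher and 2 lower. Its called ends went both ways: Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 37.2% ± 2.84 to 55.6% ± 5.07, while the Abcg8 end fell as above. Xenobiotic metabolism genes were 5.38 points higher (camera adjusted p = 1.01e-04, and 0.0179 with an estimated correlation). Adjusted over this list alone, 9 ends were higher and 1 lower. Ugt2b1, a glucuronosyltransferase gene, rose from 32.8% ± 1.48 to 53.6% ± 4.11, and Cyp2c29 from 28.1% ± 3.85 to 44.6% ± 3.75, both in gene families with close copies.

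The fructose, glucose and insulin list was 3.69 points higher (camera adjusted p = 5.31e-05, and 0.025 with an estimated correlation). Adjusted over this list alone, 6 ends were higher and 1 lower. The list of major urinary proteins and sex-biased growth hormone targets was 5.78 points higher by the mean and 2.94 by the median. The camera adjusted p was 5.31e-05, and 0.0179 with an estimated correlation. Adjusted over this list alone, 9 ends were higher and 0 lower, and Hsd3b5 was called over all ends. The list includes Mup11, whose reads may have been shared with close copies. The DNA methylation and one-carbon list was 2.31 points higher (camera adjusted p = 0.0103, and 0.0417 with an estimated correlation, 9 ends higher and 2 lower adjusted over the list alone). Its median difference was only 0.343 points, with 19 of 34 ends higher, and its call was lost with every zero left out. Its called end was at Ahcy, which clears S-adenosylhomocysteine, and rose from 50.3% ± 1.12 to 68.3% ± 3.27. Lipogenesis and fatty acid oxidation lists were 2.23 and 2.02 points higher (adjusted p = 0.0241 and 0.0201), but were not called with an estimated correlation (adjusted p = 0.0532 for each). The estimated correlations were -0.0022 and -0.0072, below the preset 0.01, so these calls were not lost to a higher correlation. With every zero left out the lipogenesis and fatty acid oxidation lists were 0.189 and 0.894 points higher and not called (camera adjusted p = 0.256 and 0.064). No end of these lists was called over all ends, and adjusted over the list alone 5 rose and 0 fell for lipogenesis and 1 rose and 0 fell for fatty acid oxidation. Lpin1 was at 69.96% ± 1.501 in ND and 79.8% ± 2.33 in NASH (adjusted p = 0.0673), Acacb at 32.1% ± 1.99 and 42.3% ± 4.27 (0.103), and Bdh1 at 29.0% ± 5.35 and 40.4% ± 5.83 (0.192).

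Markers of the other liver cell types went the other way or did not pass. Neutrophil genes were 3.62 points lower over 24 ends (adjusted p = 0.00146, and adjusted p = 0.025 with an estimated correlation), with 4 of the 24 higher in NASH. With ends reaching 2000 bases either way the neutrophil difference was -1.80 points and its call was lost (adjusted p = 0.0642). Stellate cell and matrix genes were 1.89 points lower (adjusted p = 0.0491), and this call was lost with an estimated correlation (adjusted p = 0.328). Endothelial genes were 2.94 points lower (adjusted p = 0.0538), lymphocyte genes 2.39 points lower (0.15), macrophage genes 2.03 points lower (0.1) and cholangiocyte genes 0.812 points higher (0.278), and none of these passed. No single end of these lists was called. The smallest p-values were at Mpo (72.6% ± 3.60 in ND, 61.8% ± 7.11 in NASH) and Itgb2 (69.2% ± 4.34, 59.5% ± 4.77) for neutrophils, Spp1 (55.2% ± 3.86, 44.3% ± 5.59) and Hgf (18.9% ± 1.01, 14.1% ± 3.56) for stellate cells, and C1qb (72.6% ± 2.28, 62.9% ± 4.14) and Spi1 (22.5% ± 1.85, 34.2% ± 8.04) for macrophages. They were at Cd2 (85.8% ± 2.40, 78.3% ± 3.65) and Ms4a1 (86.6% ± 2.64, 80.6% ± 3.16) for lymphocytes, Sox17 (50.3% ± 2.15, 42.2% ± 2.44) and Stab2 (86.6% ± 2.58, 90.3% ± 0.883) for endothelium, and Muc1 (69.0% ± 2.51, 60.7% ± 2.82) and Spp1 for cholangiocytes.

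**Figure D3:**
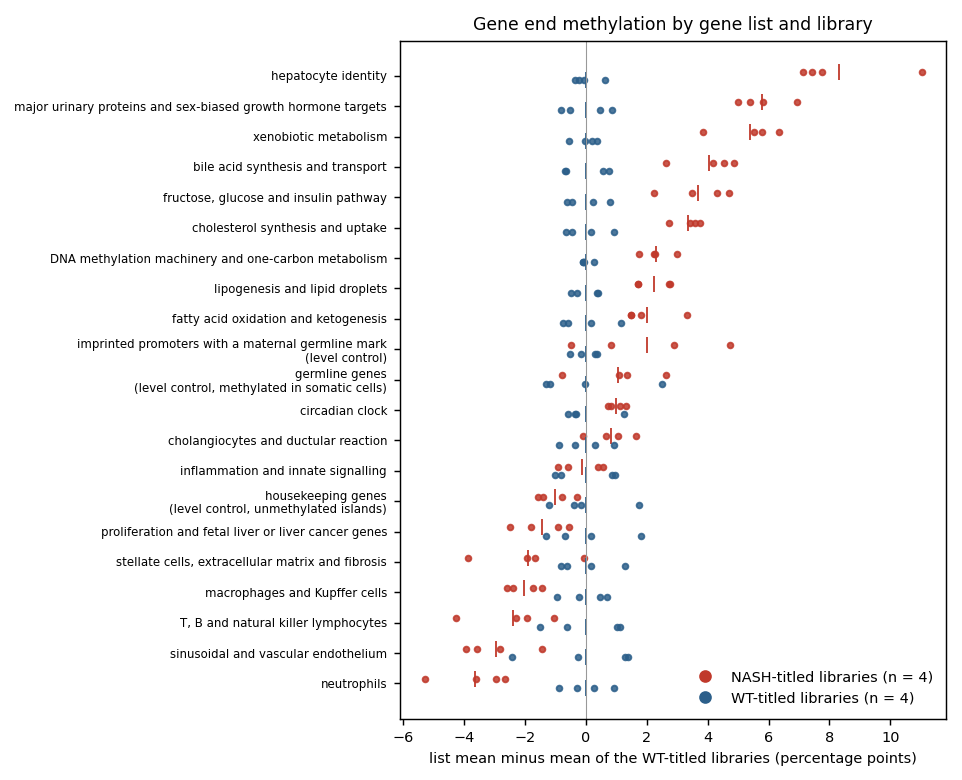
Mean methylation of the gene ends of each of the 21 lists per library, minus the mean of the ND (WT-titled) libraries, in percentage points, with a point per library and a tick at each group's mean. Hepatocyte identity lies 8.33 points above the ND mean and neutrophils 3.62 points below it.

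Inflammation genes (-0.132 points, adjusted p = 0.97), proliferation and fetal liver genes (-1.44 points, 0.278) and clock genes (1.01 points, 0.227) did not pass. For inflammation the mean was negative while the median (0.308 points) and the direction of the test were positive. The smallest p-values among inflammation genes were at Ccl3 (84.6% ± 2.88 in ND, 72.8% ± 3.49 in NASH, adjusted p = 0.0664) and Nlrp3 (81.7% ± 1.08, 74.6% ± 1.10, 0.0901), and adjusted over the list alone 2 ends fell. Among the proliferation genes they were at Trp53 (88.4% ± 1.68, 81.3% ± 3.83) and Ly6d (84.1% ± 2.35, 73.4% ± 9.86), and among clock genes at Cry1 (95.8% ± 1.40, 91.8% ± 0.409) and Tef (64.8% ± 3.37, 72.2% ± 1.43), none of them called. The level controls did not pass: germline genes had a median level of 88.3%, imprinted genes of 70.6% and housekeeping genes of 36.5%, over both gene ends (adjusted p = 0.278, 0.278 and 0.885). One imprinted gene, Grb10, was called at its low end, which rose from 34.1% ± 4.66 to 54.7% ± 4.58. Without strand, this end cannot be taken as the imprinted promoter. The smallest p-values among the other controls were at Ddx4 (92.2% ± 2.85, 85.5% ± 7.31) and Sycp1 (91.1% ± 0.963, 86.0% ± 5.74), and at Rplp0 (8.999% ± 0.512, 11.2% ± 0.489) and B2m (83.7% ± 6.02, 74.5% ± 3.66).

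Over whole gene spans, added after the data were examined, 1154 of 14546 genes were called, 789 with higher and 365 with lower methylation in NASH. The median size of the called differences was 3.65 points. Of 64 called spans that the naming rule gives, 39 lost their call with every zero left out, among them Hnf4a, Prox1, Nr1h4, Ppara, Pygl, Slc2a2, Fbp1, Nr1i3, Fmo5, Igf1, Gnmt, Srebf1, Mpo, Reln, Prf1 and Mup11 below. With same-numbered libraries treated as blocks 17 lost it, among them Srebf1, Prf1, Reln and Fga, and with doubtful zeros left out 5 did. Hepatocyte identity genes rose at 14 of 18 spans and fell at 0, among them Hnf4a (51.1% ± 0.785 in ND, 58.9% ± 1.06 in NASH), Cps1, the first enzyme of the urea cycle (53.2% ± 0.89, 64.1% ± 2.03), Prox1 (57.7% ± 0.591, 62.8% ± 0.703) and Arg1 (48.4% ± 2.47, 60.6% ± 1.44). Cholesterol synthesis genes rose at 10 of 17 spans and fell at 1, Lss (83.1% ± 0.735, 81.3% ± 0.211). Those that rose included Fdft1 (49.0% ± 0.941, 57.9% ± 0.961), Stard4 (54.0% ± 0.683, 59.8% ± 0.801) and Insig1 (32.2% ± 1.57, 43.1% ± 1.96). Bile acid genes rose at 10 of 16 spans and fell at 1, which was Abcg5 (76.9% ± 0.378, 68.2% ± 1.97), but the list was not called with an estimated correlation (adjusted p = 0.102). Rises included Slc10a1, the main bile acid uptake carrier of hepatocytes (46.5% ± 0.869, 60.9% ± 2.89), Nr1h4, the bile acid receptor (61.0% ± 0.378, 67.7% ± 1.67), and Cyp27a1 (53.0% ± 0.972, 60.7% ± 1.86).

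Single spans in other metabolic lists rose as well, though not every list passed as a whole. Fatty acid oxidation genes rose at 7 of 18 spans, including Ppara, the fatty acid receptor (47.8% ± 0.727, 56.0% ± 2.18), but the list was not called over spans with an estimated correlation (adjusted p = 0.126). Fructose, glucose and insulin genes rose at 8 of 16, including Pygl (66.2% ± 0.368, 70.3% ± 0.862), Slc2a2 (58.8% ± 0.918, 65.3% ± 1.59) and Fbp1 (47.6% ± 1.498, 54.7% ± 1.37). Xenobiotic genes rose at 8 of 13, including Nr1i3 (57.4% ± 1.91, 67.8% ± 2.10) and Fmo5 (51.0% ± 0.814, 56.8% ± 1.13). Growth hormone and major urinary protein genes rose at 9 of 19, including Igf1 (58.5% ± 0.795, 64.3% ± 0.849) and Ghr, the growth hormone receptor (70.6% ± 0.219, 74.8% ± 0.998). One-carbon genes rose at 6 of 17 and fell at 1, Dnmt3l, and that list too was not called with an estimated correlation (adjusted p = 0.263). Lipogenesis genes rose at 4 of 19, including Srebf1 (34.5% ± 0.922, 38.9% ± 0.852), but the list did not pass over spans (mean difference 0.187 points, median -0.606, adjusted p = 0.412). In the one-carbon list Gnmt, the glycine methyltransferase that uses S-adenosylmethionine, rose from 16.6% ± 2.36 to 36.5% ± 3.67, and Ahcy from 41.6% ± 0.631 to 53.1% ± 3.71. Clock genes rose at 3 of 14 spans (adjusted p of the list 0.147 with an estimated correlation).

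Among cell type markers, called spans were 2 of 12 for neutrophils, 1 of 15 for macrophages and 1 of 22 for stellate cells. Of 13 lymphocyte spans 1 rose and 1 fell, and 0 of 14 endothelial and 0 of 13 cholangiocyte spans were called. Over all spans 1154 of 14546 were called. Mpeg1 (71.7% ± 4.63, 59.0% ± 2.79), a macrophage gene, and Cd52 (86.1% ± 1.99, 71.5% ± 3.57), a leukocyte gene, fell, as did Mpo (74.5% ± 1.75, 68.2% ± 2.14), Itgb2 (84.0% ± 1.29, 80.4% ± 1.19) and Reln (81.7% ± 0.389, 79.0% ± 0.837), while Prf1 (74.0% ± 1.18, 80.5% ± 2.06) rose. Among the 12 largest span rises were Rpl32l, Serpina3k, Mup11 and Serpina1e (29.2, 21.4, 20.5 and 20.01 points), which have close copies, and the fibrinogen genes Fga and Fgg (17.7 and 17.5 points). Among the 12 largest span falls were Txnip, a glucose-responsive gene (43.7% ± 2.09, 30.5% ± 3.66), Prr13 (65.1% ± 2.25, 51.4% ± 4.75) and S100a4 (79.7% ± 2.08, 68.9% ± 3.48). By camera 14 lists were called over spans, and 5 of them held with an estimated correlation: hepatocyte identity (adjusted p = 0.0314), cholesterol (0.0177), fructose, glucose and insulin (0.0375), xenobiotic metabolism (0.0277) and growth hormone targets (0.0177). The other 9 were lost with an estimated correlation: bile acid, fatty acid oxidation, one-carbon and clock genes as given above, and neutrophil (adjusted p = 0.197), stellate cell (0.49), macrophage (0.11), lymphocyte (0.428) and endothelial genes (0.147). With every zero left out 235 spans were called, 88 higher and 147 lower. With only doubtful zeros left out there were 1240, 799 higher and 441 lower. The balance of directions thus changed only when every zero was dropped, a setting that can also remove unmethylated positions.

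No window of 1000 bases was called by limma among 1597869, with 169513 at an unadjusted p under 0.05. The same test called 0 of 100 simulated windows shifted by 20 points. Few windows were changed in that simulation, so it does not give the power for the real windows. Among windows that did not pass (adjusted p = 0.0641 for each), those with the smallest p included a pair within or beside Hsd3b5 (chromosome 3, 98644001 to 98645000, 25.2% ± 4.24 in ND and 69.1% ± 6.35 in NASH, and 98645001 to 98646000, 9.07% ± 1.53 and 35.8% ± 4.43). Others lay in Cmah (chromosome 13, 24378001 to 24379000, 40.4% ± 7.19 and 82.9% ± 3.59) and 9647 bases from Cdc42ep1 (chromosome 15, 78832001 to 78833000, 6.85% ± 2.78 and 29.9% ± 1.68). Lower in NASH were windows in Bspry (chromosome 4, 62481001 to 62482000, 74.9% ± 1.80 and 46.9% ± 2.57), 13008 bases from Tubb2b (chromosome 13, 34113001 to 34114000, 96.2% ± 3.22 and 55.9% ± 7.90) and far from genes (chromosome 3, 40038001 to 40039000, 92.8% ± 4.32 and 58.8% ± 1.28). A pair of windows on chromosome 14 (7342001 to 7343000 and 107164001 to 107165000) were listed at 0 in every NASH library and at 14.3% and 14.4% in ND, where a 0 can stand for missing reads. Of the windows the naming rule gives, 6 passed on logit levels, 7 with doubtful zeros left out and 5 with every zero left out. With the replicate block each had a limma adjusted p of 0.224.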

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

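The tests of the zeros, of library-wide level, of the hepatocyte share and of the splits were chosen after the results were seen, while the test on 5000-base windows was fixed before its values were seen. A library far from the other 3 of its group was found in 10 of 164 groups of 4, where chance gives about 8.2.

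Among lists and classes, NASH replicate 4 was high for hepatocyte identity (44.2% against 40.3% to 40.9%). ND replicate 2 was low in CpG-sparse gene ends (57.3% against 57.75% to 57.76%) and high for the one-carbon list (48.5%), and ND replicate 1 was high for clock genes (43.7%). Among gene ends, NASH replicate 2 was low at Hal (38.5% against 55.0% to 56.8%), Stab2 (89.0%) and Trp53 (75.7%). NASH replicate 1 was low at Dcun1d1 (43.7%). NASH replicate 4 was high at Uox (51.7%) and low at Sycp1 (77.5%).

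Higher methylation of hepatocyte identity genes in NASH held in tests against simple measurement faults. With every zero left out, the mean difference of the list was 6.30 points (SE 1.17 over 35 ends), so zeros written for unread positions are not the whole cause. With each library's median removed it was 8.70 points (SE 1.27 over 36 ends), and the genome-wide difference was negative, which argues against a library-wide shift. Both SEs are over ends measured in the same libraries, so they do not measure the spread between libraries. A lower share of hepatocytes in NASH liver stays open: 5 of the 6 lists of other cell types had a negative mean difference, as such a change would need, though only the neutrophil and stellate cell lists passed. The neutrophil call was lost with 2000-base ends (-1.80 points against -3.62, adjusted p = 0.0642). The stellate call was also lost there (-1.07 points), as well as with an estimated correlation (adjusted p = 0.328), with the replicate block (0.0844) and with doubtful zeros left out (0.0702). Whether one lower share could account for all called ends cannot be told apart from changes within cells. The largest lost share needed at a called end was 54.2% (SE 8.93, Eif5, named after its values were seen), and the median over the 66 ends was 27.9%. By the same formula, 11 hepatocyte identity ends with low ND levels averaged 7.72% (SD 10.3). The limit set at their mean plus 2 SD was 28.4%. Of the 11 ends, 5 had at least 80 positions. An end unmethylated in every cell type cannot show a lost share, so the limit is uncertain. Eif5 lies above that limit, as do other called ends, among them Trabd, Serpina1e and Dgkq, while the median lies below it. Eif5 is the most extreme of the 66 ends, and the comparison assumes that other cells are fully methylated at each end. A change of methylation within hepatocytes on the diet is another possible explanation, and it was not tested.

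NASH libraries had more positions at intermediate levels of 20% to 80% (28.1% ± 1.20 against 25.4% ± 0.815, n = 4 each, exact permutation p = 0.0571). Positions at exactly 100% made up 33.1% to 37.3% in NASH and 37.0% to 38.7% in ND libraries. Exact zeros made up 12.3% to 13.0% and 12.8% to 13.1%. Fewer reads per position would make fewer single positions intermediate and leave 5000-base means alone. The share of such windows at 20% to 80% was 3.59 points higher in NASH (exact permutation p = 0.286, n = 4 each), which does not decide the question, since depth is unknown.

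No other split of the libraries matched the gene end and span counts, but this does not exclude chance. The comparison has only 35 splits, and the libraries may not come from separate mice. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many called ends (88, highest other 1), and the same held for spans (1154, highest other 1). For 1000-base windows the comparison decides nothing, since the real count was 0, which all 35 splits reach by construction (highest other 3).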

How the results depend on the processing

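Handling of zeros, gene spans, minimum positions, removal of level medians and class means without 1 library were chosen after the data were examined. Causes were not tested except where named. Not run for want of read counts: at least 10 reads per CpG, minimum 10 or 50 reads, read-weighted means and the quasi-binomial model. Autosomes alone were already all that was analysed. The depth limit is unknown.

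The genome-wide difference kept its sign under every setting run. It moved most, from -0.423 to -0.878 (exact permutation p = 0.114), with every zero left out. Without 1 library it ranged from -0.707 (without NASH replicate 3) to -0.279 (without NASH replicate 2), and was -0.676 without ND replicate 2. Without 1 library the classes ranged from -0.222 to 0.0277 (CpG-dense gene ends), -0.172 to 0.132 (CpG-dense elsewhere), -0.293 to 0.0548 (CpG-sparse gene ends), -0.521 to -0.121 (inside genes) and -1.11 to -0.518 (intergenic). With every zero left out CpG-dense gene ends reversed to 0.0915, and the others moved to -0.310 (CpG-dense elsewhere), -0.989 from -0.0817 (CpG-sparse gene ends), -0.801 from -0.259 (inside genes) and -1.03 from -0.729 (intergenic), none of them past the threshold.

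Called gene ends numbered 88 (66 higher, 22 lower). They were 278 on logit levels, 321 with library medians of logit levels removed, 254 with medians of levels removed (203 higher, 51 lower), 109 with doubtful zeros left out, 891 with 2000-base ends and 0 with every zero left out (3313 at unadjusted p under 0.05). Without 1 library they ranged from 2 to 15 (9, 15, 8 and 4 without NASH replicates 1 to 4, and 2, 4, 6 and 4 without ND replicates 1 to 4), from fewer libraries. The replicate block gave 0 by limma (3433 at unadjusted p under 0.05) and 474 spans. By deviations from group means, same-numbered libraries correlated at 0.0027 to 0.0288 at ends and -0.0248 to 0.0711 over spans. Libraries of different numbers correlated at -0.0388 to 0.0195 at ends and -0.0743 to 0.0509 over spans. These values do not settle whether the numbers pair the libraries.

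Called windows, 0 as reported, were 11 on logit levels, 403 with logit medians removed, 3482 at 5000 bases, 127 with doubtful zeros left out, 1663 with every zero left out, 308 with at least 12 positions, and 0 to 2 without 1 library. Called spans, 1154 as reported (789 higher, 365 lower), were 84 at 10 points or more, 235 with every zero left out (88 higher, 147 lower), and 607 to 1086 without 1 library: 638 without NASH replicate 4, 607, 752 and 739 without ND replicates 1, 3 and 4. Without NASH replicate 3 they were 633 higher and 453 lower. With doubtful zeros left out 1240 were called, 799 higher and 441 lower.

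Of the lists, 11 were called, and 9 to 12 without 1 library. With an estimated correlation lipogenesis (2.23), fatty acid oxidation (2.02) and stellate cells (-1.89) lost their calls. With every zero left out lipogenesis (0.189), fatty acid oxidation (0.894), stellate cells (-1.69) and one-carbon (2.13) lost theirs, macrophages (-3.25), lymphocytes (-3.23) and endothelium (-3.16) gained one, and cholangiocytes (-0.926) and clock (-0.763) reversed. On spans lipogenesis (0.187) lost its call, macrophages (-2.24), lymphocytes (-1.73), endothelium (-0.922) and clock (1.63) gained one, which none of the 4 held with an estimated correlation (adjusted p = 0.11, 0.428, 0.147 and 0.147), and cholangiocytes (-0.775) and housekeeping (0.0852) reversed. With 2000-base ends stellate cells (-1.07) and neutrophils (-1.80) lost theirs, clock (1.13) gained one and cholangiocytes (-0.324) reversed. With doubtful zeros left out stellate cells (-1.79) lost theirs and macrophages (-2.66) gained one, and the replicate block ended the stellate call (-1.89).

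Without 1 library the ranges were 2.05 to 2.40 for lipogenesis (lost without NASH replicate 4 and ND replicates 1 and 4), 1.59 to 2.41 for fatty acid oxidation (lost without ND replicate 3), -2.50 to -1.22 for stellate cells (lost without NASH replicates 1 and 4 and ND replicates 3 and 4), -2.35 to -1.81 for macrophages (called without ND replicate 4), -3.76 to -2.48 for endothelium (called without NASH replicate 1 or ND replicate 2) and -0.469 to 0.187 for inflammation (reversed without NASH replicate 1 or 4 or ND replicate 1 or 3). Lists that were not called also moved: proliferation ranged from -1.87 to -0.837 (the latter without ND replicate 3), cholangiocytes from 0.523 (without ND replicate 2, and 0.538 without NASH replicate 3) to 1.12, germline genes from 0.546 to 1.91, imprinted genes from 1.08 (without NASH replicate 1) to 2.83 and housekeeping genes from -1.42 to -0.439 (the latter without ND replicate 3). The lowest stellate size, -1.22, was without NASH replicate 4.

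All 34 called named ends stayed called on logit levels. Of them 8 lost the call with doubtful zeros left out, and all 34 with every zero left out or with the replicate block. Leaving out 1 library in turn ended the call of a named end in 240 comparisons. With every zero left out Acacb (-2.71) and Spi1 (-5.80) reversed. Of 64 called named spans 39 lost the call with every zero left out, 17 with the replicate block, 5 with doubtful zeros left out and 2 on logit levels, and leaving out 1 library ended a call in 80 comparisons and left it in 432.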

Other observations

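Longer windows, an alternative planned before the data were examined, showed where the differences gathered, and the genes below were picked after their values were seen. Of 364103 windows of 5000 bases, 2194 were called higher and 1288 lower in NASH. Of those called higher 81.7% lay in protein-coding genes, against 43.2% of all windows and 57.1% of those called lower. Windows called higher had a median ND level of 52.8%, those called lower one of 86.1%, and all windows one of 79.7%. Genes with the most called windows were Cps1 (18 of 23 windows higher, 0 lower), Egfr (18 of 33), Ttc39c (18 of 32), Rbm47 (13 of 28), Mtss1 (12 of 29), Adk (11 of 80) and Rxra, a partner of many nuclear receptors (11 of 18). Ghr had 10 of 54 and Cat, the catalase gene, 7 of 8. Counts of lower windows were smaller, the largest being 5 of 113 in Pkhd1, and Fnbp1 was among the genes with 4 (of 25). Erg, an endothelial transcription factor gene, and Fyb, a leukocyte adaptor gene, each had 3 lower and 0 higher.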
